A study of Mus musculus with 6 samples.

How the data were processed

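RNA was taken from cells labelled as hematopoietic stem cells, sorted from bone marrow of wild-type mice aged 12 months by the level of surface MHCII, with 3 libraries of the MHCII-hi and 3 of the MHCII-lo fraction. Groups and replicate numbers follow the labels. The markers and gates of the sort, the number of animals and whether libraries of a group came from separate animals are not given in the sources used here. Per the labels' protocols, RNA was extracted with a column kit for small samples and libraries were made with a stranded mRNA kit, which captures polyadenylated transcripts. The submitters' processing notes name fastp, HISAT2 and StringTie and the mouse build GRCm38 (mm10), without versions, and whether the quantification used strand is not stated.

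The authors deposited 1 table per library with a gene name and 1 value for each of 30803 genes. The unit of these deposited values was inferred to be FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library): the values have 2 decimals, their sums per library of 327364 to 346651 are not a fixed total as in TPM, and StringTie writes FPKM. No header names the unit. FPKM are relative values, so an abundant set of genes that takes more of a library lowers all others, and the 10 most abundant genes took 11.6 to 11.7% of summed FPKM in MHCII-lo and 19.4 to 19.5% in MHCII-hi. Depth was sought from the step that 1 fragment would give in low values of single-exon genes of 600 to 4000 bases, but no clear step was found (mean cosine 0.0586 to 0.152 by library), so depth is unknown and no counting intervals are given. No count model was used, since the tables hold no counts.

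Of the 30803 genes, 3888 were at 0 in all libraries. Symbols were repeated in 70 extra rows, for which the row with the highest mean kept the symbol. Genes with a mean of at least 1 FPKM over the 6 libraries were tested (12049). Values were taken as log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3 with an intensity trend, group as the only term, and Benjamini-Hochberg adjustment over the tested genes at 0.05. With 34 gene lists (1028 entries, of which 21 were not found and 1 was matched through a synonym), fixed before the data were examined, each list with at least 5 tested members was tested with fry, and beside it with camera, with a preset correlation of 0.01 between genes and with an estimated correlation. Fry tests whether genes of a list move, on balance, in 1 direction. Camera compares them with the other genes. Adjusted p-values of lists are over the 32 lists tested. Gene positions come from GENCODE annotation of GRCm38. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 served for the other steps.

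The fit was tested on simulated data for this comparison, with 12049 genes of the real means and residual spreads and 200 changed genes. It recovered 46% of genes changed 1.25-fold, 78% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, and 13 of 171 calls (7.6%) were false. The real comparison called 7334 genes, with a median log2 fold change of −0.12 over all tested genes, which the simulation did not copy. Its spreads came from libraries that may be technical repeats, so these shares need not hold for the real calls.

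Named genes followed a rule fixed before the data were examined. It took the sort check genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74; the 10 genes with the largest fold change in each direction among those with an adjusted p under 0.05 and values of the 3 libraries of one group wholly above those of the other, leaving out predicted genes (Gm and Rik names) and class II genes; and the 4 members with the smallest p of each list called by fry or with at least 2 called members, or else the member with the smallest p. This gave 147 genes, of which a part is named. Genes named outside the rule are said to have been chosen after their values were seen. A further 4 lists of granulocyte genes were drawn up after the data were seen and are described only in the closing observations. Alternatives were another pseudocount, filter, scaling or variance model, the replicate number as a block, leaving out each library, and camera in place of fry; median centring and a total without granulocyte genes were added after the data were seen.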

Results

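Hematopoietic stem cells (HSCs) are the bone marrow cells from which all blood lineages arise, and MHC class II (MHCII) is the antigen-presenting complex of dendritic cells, B cells and macrophages. Transcript levels were measured by RNA sequencing in cells labelled as HSCs, sorted from the marrow of wild-type mice aged 12 months into a fraction with high surface MHCII (MHCII-hi) and a fraction with low surface MHCII (MHCII-lo). Each fraction had 3 libraries. The tables held 30803 genes in FPKM, and between 21184 and 21552 genes per library lay above 0. Between 11989 and 12065 genes per library reached 1 FPKM. The number of reads per library is unknown, since FPKM values carry no depth. Correlations of log2 values across the 12049 tested genes were 0.992 to 0.993 within MHCII-lo, 0.991 to 0.993 within MHCII-hi and 0.945 to 0.947 between the fractions. The first principal component held 82.7% of the variance and parted the fractions. The median coefficient of variation between libraries of a group was 9.12% in MHCII-lo and 9.75% in MHCII-hi for genes of 1 to 5 FPKM, and 1.30% and 1.16% for genes of 500 FPKM and above. Nothing in the labels says that the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Values below are the mean ± SD of FPKM over 3 libraries per group, in the order MHCII-lo to MHCII-hi, and log2 fold changes are MHCII-hi minus MHCII-lo on the log2(FPKM + 1) scale, which understates the change of low genes.

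The transcripts behind the sorted protein were measured first, since they check the labels. The 4 class II genes set as the sort check were all higher in MHCII-hi. H2-Eb1, the beta chain of the I-E molecule (chromosome 17, 34305867 to 34316674, GRCm38), went from 6.30 ± 0.404 to 15.8 ± 0.786 FPKM (log2 fold change 1.21, SE 0.0559, limma adjusted p 3.44e-06). H2-Aa (chromosome 17, 34282744 to 34287823) went from 7.603 ± 0.533 to 13.7 ± 1.09 FPKM and H2-Ab1 (chromosome 17, 34257689 to 34269419), the chains of the I-A molecule, from 11.1 ± 0.479 to 18.9 ± 0.7302 FPKM. Cd74, the invariant chain (chromosome 18, 60803848 to 60812652), went from 56.2 ± 1.47 to 77.1 ± 1.98 FPKM, a ratio of 1.37. Genes of peptide loading onto class II were lower or did not pass the test. H2-DMa was 2.34 times lower in MHCII-hi (16.8 ± 0.885 to 7.17 ± 0.344 FPKM, log2 fold change −1.12, adjusted p 3.41e-06), and H2-DMb1 (18.8 ± 0.766 to 11.6 ± 1.2503 FPKM) and H2-Oa (3.75 ± 0.526 to 2.42 ± 0.305 FPKM), chosen after their values were seen, were lower as well. H2-DMb2 (2.68 ± 0.279 to 2.85 ± 0.305 FPKM, adjusted p 0.5314) and H2-Ob (1.63 ± 0.112 to 1.77 ± 0.1804 FPKM, adjusted p 0.4271), chosen in the same way, did not pass the limma test. Of the 12 tested members of the class II list, 4 were higher and 3 lower. The list's median was −0.03 (0.07 after median-ratio scaling, −0.0654 without MHCII-hi replicate 2 and above 0 without MHCII-hi replicate 1) and its mean 0.05. Fry gave an upward call (adjusted p 0.0338) that was lost with an estimated correlation (camera adjusted p = 0.5796). It was also lost without MHCII-lo replicate 1, 2 or 3 (adjusted p 0.0996, 0.2002 and 0.0631) and without MHCII-hi replicate 3 (0.3959), and with the replicate number as a block (0.0519). Ciita, the master regulator of class II transcription, was at 0.243 ± 0.0115 to 0.543 ± 0.0777 FPKM, under the expression limit for testing. B cells also carry class II. Of 22 B cell markers only 8 could be tested, and 5 of these were higher in MHCII-hi and none lower. Neutrophil markers took 2.97% and 16.6% of summed FPKM.

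**Figure D1:**
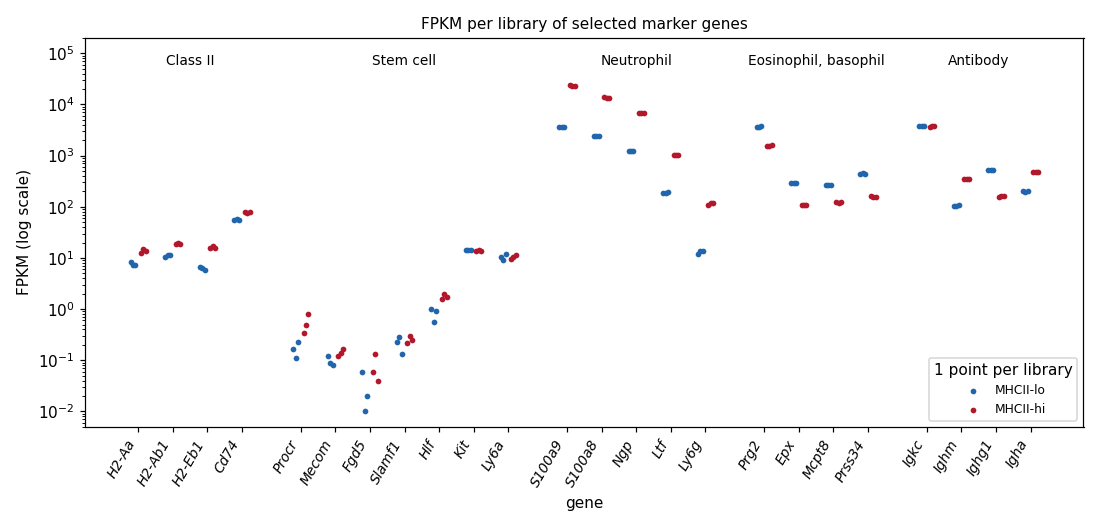
FPKM of single genes in each of the 6 libraries on a log axis, with MHCII-lo in blue and MHCII-hi in red, 1 point per library, grouped as class II, stem cell, neutrophil, eosinophil or basophil, and antibody genes. S100a9 stood at 3598 ± 25.01 FPKM in MHCII-lo and 23315 ± 260.3 in MHCII-hi, while Procr, Mecom, Fgd5 and Slamf1 lay under 1 FPKM in all 6 libraries.

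The comparison of the fractions asked which transcripts differ between cells labelled as HSCs with high and with low MHCII at middle age. Of the fixed gene lists, neutrophil markers had the highest median change in MHCII-hi, and genes of ribosomes, respiration, DNA replication and the red cell lineage were lower. All 22 neutrophil markers were higher in MHCII-hi, by a median log2 fold change of 2.77 (2.89 relative to the median gene), and none was lower, also under 4 other scalings. Of 12049 tested genes, 2451 were higher and 4883 lower in MHCII-hi at a limma adjusted p under 0.05. Of these, 446 were at least 2-fold higher and 164 at least 2-fold lower. In 67.6% of the tested genes the 3 values of one group lay wholly above those of the other, against 10% by chance. The median log2 fold change of all tested genes was −0.12, and it was −0.01 after median-ratio scaling, so list medians are given also relative to the median gene. The split of calls moved with this shift: 33.4% of called genes were higher as deposited, 41.2% after quantile normalization (2819 higher, 4025 lower), 45.0% after median centring (2999 and 3672), 52.1% after median-ratio scaling (3394 and 3123) and 52.7% when granulocyte genes were left out of the total (3434 and 3081).

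Among the 10 genes with the largest increases, 6 belonged to the stefin A family of cysteine protease inhibitors, which mature neutrophils express. Stfa2 went from 2.67 ± 0.168 to 193 ± 6.58 FPKM (log2 fold change 5.72, SE 0.0439, adjusted p 1.12e-09), Stfa3 from 1.47 ± 0.2702 to 119 ± 9.09 FPKM and Stfa1 from 2.06 ± 0.0814 to 89.9 ± 4.42 FPKM. Stfa2l1 went from 9.83 ± 0.392 to 224 ± 14.9 FPKM, Cstdc5 from 1.94 ± 0.448 to 139.5 ± 4.19 FPKM and Cstdc4 from 1.15 ± 0.2996 to 60.96 ± 3.92 FPKM. The 4 Stfa genes lie within 36156811 to 36455392 of chromosome 16 and are near-identical copies, so how reads were shared among them, and with Cstdc4 and Cstdc5, is uncertain. The other 4 included Asprv1, a retroviral-like protease (3.36 ± 0.567 to 161 ± 4.15 FPKM), and Slfn4, a myeloid Schlafen gene (19.9 ± 0.894 to 322 ± 4.91 FPKM). They also included Olfm4, which marks a subset of neutrophils (5.58 ± 0.391 to 90.8 ± 0.522 FPKM), and Cxcr2, the chemokine receptor that draws neutrophils out of the marrow (7.66 ± 0.5405 to 111 ± 1.44 FPKM). The 10 genes with the largest decreases held 5 immunoglobulin genes. Igkv1-122 fell from 18.5 ± 2.403 to 2.85 ± 0.676 FPKM, Igkv4-62 from 11.4 ± 1.02 to 1.76 ± 0.737 FPKM, Ighv15-2 from 12.6 ± 1.13 to 2.44 ± 0.3798 FPKM and Igkv14-100 from 45.6 ± 4.76 to 13.2 ± 1.897 FPKM. Such V genes resemble each other, and their values are uncertain for that reason. Ighg1, an IgG heavy chain constant gene, fell from 529 ± 5.13 to 160.1 ± 2.79 FPKM (log2 fold change −1.72, SE 0.0189, adjusted p 5.90e-09). The remaining decreases included Irf8, a transcription factor of monocytes and dendritic cells (42.1 ± 0.714 to 12.3 ± 0.464 FPKM), and Prg3, an eosinophil granule protein (165 ± 1.84 to 49.98 ± 4.22 FPKM). The others were Fcgrt, the neonatal Fc receptor (9.72 ± 0.549 to 2.20 ± 0.0954 FPKM), Cnn3, a calponin (6.32 ± 0.603 to 1.15 ± 0.1102 FPKM), and Clec4b1, a lectin of dendritic cells (3.34 ± 0.393 to 0.357 ± 0.108 FPKM).

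The neutrophil genes were also among the most abundant transcripts. Their 22 markers made up 2.97 ± 0.017% of summed FPKM in MHCII-lo and 16.6 ± 0.042% in MHCII-hi, and fry called the list (adjusted p 1.84e-10), as did camera with an estimated correlation (adjusted p = 0.01). S100a9 and S100a8, which form calprotectin, went from 3598 ± 25.01 to 23315 ± 260.3 FPKM and from 2432 ± 6.76 to 13603 ± 292 FPKM. Ngp, a granule protein, went from 1213 ± 10.7 to 6830.0 ± 84.2 FPKM, and Chil3, a chitinase-like protein, from 692 ± 3.67 to 2312 ± 12.4 FPKM. Ly6g, the surface antigen used to stain neutrophils and chosen after its values were seen, went from 13.1 ± 1.08 to 115 ± 4.499 FPKM. The list of granulocyte and monocyte priming, which holds genes of earlier stages, went both ways, with 12 of 27 higher and 12 lower. Its median of −0.02 turned to 0.11 after median-ratio scaling, its mean was 0.10, and fry's upward call (adjusted p 0.000203) had an adjusted p = 0.5756 with an estimated correlation. Csf3r, the receptor for the neutrophil growth factor G-CSF, went from 40.5 ± 1.02 to 143 ± 3.02 FPKM, Cd33 from 6.19 ± 0.2003 to 51.7 ± 1.49 FPKM and Hp, haptoglobin, from 286 ± 3.94 to 648 ± 4.1996 FPKM. Mpo and Elane, enzymes of primary granules chosen after their values were seen, fell from 2044 ± 22.95 to 1566 ± 5.95 FPKM and from 1708 ± 29.5 to 1331 ± 0.948 FPKM.

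In the lists of mast cell, dendritic cell, monocyte, T and NK cell and stromal markers, more genes were lower than higher in MHCII-hi. Of 11 mast cell and basophil markers, 7 were lower in MHCII-hi and 1 higher. The mast cell and basophil median was −0.36 (−0.24 relative to the median gene), at an adjusted p of 1.35e-06 by fry and an adjusted p = 0.3076 with an estimated correlation. The basophil proteases Prss34 and Mcpt8 fell from 440.3 ± 11.02 to 159 ± 3.46 FPKM and from 270.0 ± 0.596 to 121 ± 2.61 FPKM, and Hdc, which makes histamine, rose from 24.4 ± 0.583 to 47.8 ± 0.943 FPKM. Dendritic cell markers were lower in 13 of 17 and higher in 3. For dendritic cell genes the median was −0.60 (−0.48 relative to the median gene), with a fry adjusted p of 2.04e-05 and an adjusted p = 0.1797 with an estimated correlation. Cst3 fell from 212 ± 3.79 to 126 ± 2.41 FPKM, while Plbd1 rose from 37.7 ± 2.19 to 108 ± 2.88 FPKM. Of 13 monocyte and macrophage markers, 7 were lower and 3 higher. The monocyte and macrophage median was −0.29 (−0.17 relative to the median gene), at an adjusted p of 3.32e-05 by fry and an adjusted p = 0.5325 with an estimated correlation. The median was −0.10 (−0.03 relative) under quantile normalization and −0.05 (−0.03 relative) without a filter on low values. It was −0.36 (−0.24 relative) without MHCII-hi replicate 1. Csf1r, the receptor for the macrophage growth factor, fell from 42.3 ± 1.36 to 19.7 ± 1.12 FPKM, and Ccr2 fell from 60.3 ± 0.993 to 30.5 ± 0.404 FPKM. T and NK cell markers were low, and 8 of 17 were lower and none higher. Across T and NK cell genes the median came to −0.28 (−0.16 relative to the median gene). The fry adjusted p was 3.32e-05, with an adjusted p = 0.2423 with an estimated correlation. Ccl5, a chemokine, fell from 28.2 ± 2.33 to 13.2 ± 1.63 FPKM. Of the 6 stromal and bone markers tested, 3 were lower and 2 higher. For stromal and bone genes the median was −0.19 (−0.08 relative to the median gene), with a fry adjusted p of 0.000239 and an adjusted p = 0.9269 with an estimated correlation. Fn1, fibronectin, fell from 134 ± 0.838 to 65.3 ± 1.88 FPKM. Only 4 of 20 endothelial markers reached the expression limit, too few for a list test, and 3 of them were lower. These were Eng (6.32 ± 0.0458 to 3.33 ± 0.0981 FPKM), Pecam1 (12.2 ± 0.338 to 7.27 ± 0.486 FPKM) and Tie1 (2.37 ± 0.0289 to 1.803 ± 0.145 FPKM), of which Tie1 lost its call after median-ratio scaling (adjusted p 0.0556) and with granulocyte genes left out of the total (0.0577). Of 4 tested sex-linked genes, Ddx3y and Eif2s3y on the Y chromosome were higher, at 15.8 ± 1.12 to 17.5 ± 0.352 FPKM and at 20.5 ± 0.264 to 22.1 ± 0.436 FPKM. The call for Ddx3y was lost without any library but MHCII-lo replicate 1, with adjusted p of 0.0636 to 0.1246, without a filter on low values (0.0863) and without an intensity trend (0.059). For Eif2s3y it was lost without MHCII-lo replicate 1 (0.0559) and MHCII-hi replicate 1 (0.0558) and with the replicate block (0.0501). Xist stayed at or under 0.02 FPKM in all 6 libraries. In the same libraries the neutrophil markers took 2.97% of summed FPKM in MHCII-lo and 16.6% in MHCII-hi.

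Antibody genes were abundant in both fractions and differed by class. Igkc, the kappa light chain constant gene, was chosen after its values were seen. It stood at 3718 ± 11.97 FPKM in MHCII-lo and 3695 ± 20.2 in MHCII-hi (limma adjusted p 0.4252). Of 22 B cell markers, only 8 reached the expression limit. The median marker of all 22 stood at 0.537 ± 0.0375 FPKM in MHCII-lo and 0.590 ± 0.0794 in MHCII-hi. Of the 8 tested, 5 were higher in MHCII-hi and none lower, although 1 was lower under quantile normalization. The median log2 fold change of the tested B cell markers was 0.76 (0.88 relative to the median gene). Fry gave an adjusted p of 1.46e-05, with an adjusted p = 0.1811 with an estimated correlation. Ighm, the IgM heavy chain, went from 107 ± 2.61 to 349 ± 4.21 FPKM, and Pou2af1, a B cell coactivator, from 2.25 ± 0.0586 to 7.15 ± 0.591 FPKM. Cd24a, which other blood cells also carry, went from 187 ± 1.62 to 317 ± 3.88 FPKM. Of 13 plasma cell markers, 8 were higher and 3 lower. Their median was 0.33, but fry leaned downward without a call (adjusted p 0.5309) and called the list upward under all 4 other scalings. Camera gave an upward call with a preset correlation (adjusted p 0.0267) that was lost with an estimated correlation (adjusted p = 0.174). Without single libraries fry called the list upward (MHCII-lo replicate 1, adjusted p 0.000978, and replicate 2, 0.0102) or downward (MHCII-hi replicate 2, 0.0337). It also called the list downward with a pseudocount of 5 (adjusted p 0.0304) and at a mean of at least 5 FPKM (0.0103). Igha, the IgA heavy chain, rose from 202 ± 6.07 to 483 ± 5.15 FPKM, and Ighg2c rose from 616 ± 13.1 to 773 ± 13.04 FPKM. Ighg2b fell from 479 ± 2.22 to 248 ± 4.64 FPKM.

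Genes that define stem cells had a median of 1.39 ± 0.033 FPKM in MHCII-lo and 1.61 ± 0.067 in MHCII-hi, and those that could be tested moved both ways. Of 40 stem cell identity genes, 15 stayed under 1 FPKM in all 6 libraries. Several genes were chosen here after their values were seen. The surface markers Procr (0.170 ± 0.0600 to 0.543 ± 0.228 FPKM) and Slamf1 (0.217 ± 0.0808 to 0.257 ± 0.0404 FPKM) were not tested, being under the expression limit. The regulators Mecom (0.0967 ± 0.0208 to 0.143 ± 0.0252 FPKM), Fgd5 (0.0300 ± 0.0265 to 0.0767 ± 0.0473 FPKM) and Hoxb5 (0.0467 ± 0.0404 to 0.0400 ± 0.0173 FPKM) were not tested for the same reason. Kit (14.3 ± 0.175 to 13.9 ± 0.318 FPKM) and Ly6a, which encodes Sca-1 (10.4 ± 1.27 to 10.4 ± 1.07 FPKM), did not pass the test. Hlf was higher (0.827 ± 0.233 to 1.75 ± 0.186 FPKM, limma adjusted p 0.0042). Cd34, a sorting marker named by the rule, was lower (15.4 ± 0.411 to 11.6 ± 0.230 FPKM, limma adjusted p 0.000109). Of the 25 tested genes of the list, 9 were higher and 9 lower. The median was −0.05, turning to 0.08 after median-ratio scaling, and the mean was 0.14. Fry called the list upward (adjusted p 0.000139), with an adjusted p = 0.3076 with an estimated correlation. Erg went from 8.68 ± 0.372 to 14.6 ± 0.125 FPKM. Ifitm1, also an interferon-induced gene, went from 25.5 ± 1.78 to 128 ± 2.504 FPKM.

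Among markers used to sort stem cells, 2 of 7 tested were higher and 3 lower. Their median was −0.05, or 0.08 after median-ratio scaling and −0.0822 to −0.0368 without single libraries. Fry's downward call (adjusted p 0.0233) was lost under the other scalings, without a filter on low values (0.59), with a replicate block (0.2207) and with an estimated correlation (adjusted p = 0.9229). It was also lost without MHCII-lo replicate 1 (0.0915) or MHCII-hi replicate 1 (0.0669). Cd48, which is absent from long-term HSCs, fell from 107 ± 4.78 to 50.7 ± 2.03 FPKM, and Flt3, a marker of multipotent progenitors, from 12.1 ± 0.0473 to 7.64 ± 0.422 FPKM. Of 49 genes of a stem cell ageing signature, 24 could be tested. Among these, 7 were higher and 10 lower (11 lower adjusted over the list alone). Fry gave no call (adjusted p 0.5) with a median of −0.12 and a mean of 0.05, but an upward call under 4 other scalings. It called the list downward without MHCII-lo replicate 2 (adjusted p 0.0330) and upward without MHCII-hi replicate 2 (0.0272), without a filter on low values (0.0012) and with a replicate block (0.0230). Gda, guanine deaminase, rose from 66.1 ± 1.17 to 144 ± 2.27 FPKM, and Jun fell from 424 ± 6.699 to 281 ± 4.66 FPKM. Lymphoid priming genes split into 9 higher and 8 lower of 23, led by Cd52 (101 ± 2.01 to 215 ± 2.84 FPKM). Their median was 0.06 (0.0304 to 0.0881 without single libraries) and their mean −0.000318. Fry's upward call (adjusted p 0.0059) had an adjusted p = 0.3777 with an estimated correlation. It was lost without MHCII-hi replicate 1 (adjusted p 0.0557) and without MHCII-hi replicate 3 (0.2981). Beside these lists, the neutrophil markers took 2.97% and 16.6% of summed FPKM.

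The red cell program was lower in MHCII-hi. Of 27 erythroid genes, 25 were lower and none higher. The erythroid median was −0.56 (−0.44 relative to the median gene), at an adjusted p of 2.26e-06 by fry and an adjusted p = 0.0386 with an estimated correlation. Car1 and Car2, carbonic anhydrases of red cell precursors, fell from 152 ± 1.899 to 86.5 ± 4.18 FPKM and from 109.9 ± 0.592 to 47.9 ± 1.98 FPKM. Aqp1, a water channel, fell from 47.4 ± 0.289 to 18.6 ± 0.8997 FPKM. Of 23 megakaryocyte and platelet genes, 11 were higher (12 adjusted over the list alone) and 6 lower. For megakaryocyte and platelet genes the median was 0.21 (0.33 relative to the median gene), with a fry adjusted p of 6.09e-05 and an adjusted p = 0.1348 with an estimated correlation. Nfe2, a regulator of platelet formation, went from 29.8 ± 0.967 to 49.5 ± 1.16 FPKM, Plek from 50.8 ± 0.159 to 82.8 ± 0.682 FPKM and Cd9 from 24.6 ± 0.906 to 54.1 ± 3.58 FPKM. The difference between these lists was not tested. In these libraries the share of neutrophil markers in summed FPKM was 2.97% and 16.6%.

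Genes of ribosomes, respiration and DNA replication were lower in MHCII-hi nearly throughout. Of 79 ribosomal protein genes, 78 were lower and none higher, under each of 4 other scalings as well. The ribosomal protein median was −0.53 (−0.41 relative to the median gene), at an adjusted p of 1.35e-06 by fry and an adjusted p = 0.0468 with an estimated correlation. Rplp1 fell from 1424 ± 24.5 to 872 ± 13.1 FPKM, Rpl13a from 467 ± 5.81 to 287 ± 1.84 FPKM and Rps29 from 408 ± 5.27 to 224 ± 2.28 FPKM, all of which can share reads with pseudogenes. Of 77 nuclear genes of oxidative phosphorylation, 71 were lower and none higher, with 1 higher under median-ratio scaling. For oxidative phosphorylation genes the median was −0.34 (−0.22 relative to the median gene), with a fry adjusted p of 5.58e-06 and an adjusted p = 0.0386 with an estimated correlation. Ndufb11, a subunit of complex I, fell from 81.7 ± 1.59 to 56.003 ± 0.432 FPKM. All 13 mitochondrially encoded genes were lower, 12 of them under quantile normalization. Across mitochondrially encoded genes the median came to −0.52 (−0.40 relative to the median gene). The fry adjusted p was 1.09e-05, with an adjusted p = 0.2423 with an estimated correlation. The respiratory subunit gene mt-Co3 fell from 2801 ± 23.4 to 2104 ± 16.998 FPKM. Of 46 genes of S phase and replication, 43 were lower (45 adjusted over the list alone) and none higher. The S phase median was −0.35 (−0.23 relative to the median gene), at an adjusted p of 1.58e-06 by fry and an adjusted p = 0.0378 with an estimated correlation. Pcna, the replication clamp, fell from 186 ± 4.24 to 129 ± 1.65 FPKM, and Mcm6, part of the replicative helicase, from 88.97 ± 1.22 to 62.7 ± 0.845 FPKM. Of 47 G2 and M phase genes, 33 were lower (34 adjusted over the list alone) and 1 higher. After median-ratio scaling 4 were higher. For G2 and M phase genes the median was −0.22 (−0.10 relative to the median gene), with a fry adjusted p of 2.14e-05 and an adjusted p = 0.1194 with an estimated correlation. Cks2, a partner of cyclin-dependent kinases, fell from 199.7 ± 0.863 to 156 ± 4.48 FPKM. Myc and translation control genes were lower in 18 of 29 and higher in 3. Across myc and translation genes the median came to −0.13 (−0.01 relative to the median gene). The fry adjusted p was 6.08e-05, with an adjusted p = 0.2423 with an estimated correlation. The relative median ran from −0.0257 to −0.0063 without single libraries and was 0.0066 after median-ratio scaling. Lower genes of this list numbered 10 after median centring, 7 after median-ratio scaling and 6 with granulocyte genes left out of the total. Fry's downward call turned upward under the last 2 (adjusted p 0.0443 and 0.0281). Npm1, a nucleolar protein, fell from 345 ± 5.004 to 277 ± 5.72 FPKM, and Max, the partner of Myc, rose from 27.5 ± 1.31 to 44.8 ± 0.502 FPKM. The neutrophil markers moved the other way, from 2.97% of summed FPKM in MHCII-lo to 16.6% in MHCII-hi.

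Glycolysis and hypoxia genes were mostly higher in MHCII-hi, 18 of 32 against 6 lower (19 and 7 adjusted over the list alone). Lower genes numbered 3 after median-ratio scaling and 3 to 6 without single libraries. The glycolysis and hypoxia median was 0.22 (0.34 relative to the median gene), at an adjusted p of 3.86e-06 by fry and an adjusted p = 0.0868 with an estimated correlation. The glucose transporter gene Slc2a3 rose from 12.1 ± 0.311 to 63.5 ± 1.71 FPKM, the lactate exporter gene Slc16a3 from 6.09 ± 0.275 to 33.7 ± 0.885 FPKM and Pfkfb4 from 6.56 ± 0.274 to 21.8 ± 0.577 FPKM. Cell cycle inhibitors and quiescence factors were higher in 14 of 31 and lower in 10 (11 lower adjusted over the list alone). For cell cycle inhibitor and quiescence genes the median was 0.04 (0.16 relative to the median gene), with a fry adjusted p of 9.25e-06 and an adjusted p = 0.2057 with an estimated correlation. Btg1, an antiproliferative gene, rose from 65.6 ± 0.951 to 115 ± 1.09 FPKM and Klf2 from 76.4 ± 2.25 to 148 ± 0.303 FPKM, while Klf4 fell from 58.9 ± 2.13 to 30.1 ± 0.594 FPKM. Targets of p53 split evenly into 10 higher (11 adjusted over the list alone) and 10 lower of 24. Across p53 target genes the median came to 0.06 (0.18 relative to the median gene). The fry adjusted p was 0.000457, with an adjusted p = 0.3076 with an estimated correlation. Without single libraries the p53 median ran from 0.0402 to 0.0932. Trp53inp1 rose from 8.37 ± 0.0971 to 29.04 ± 0.494 FPKM, and Cdkn1a, the p21 cell cycle inhibitor, fell from 19.6 ± 0.594 to 10.3 ± 0.308 FPKM. Neutrophil markers again stood at 2.97% and 16.6% of summed FPKM.

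Genes of class I presentation were lower in MHCII-hi, with 16 of 20 lower and 1 higher, or 3 higher after median-ratio scaling. The class I presentation median was −0.31 (−0.19 relative to the median gene), at an adjusted p of 2.19e-06 by fry and an adjusted p = 0.1298 with an estimated correlation. B2m, the light chain of class I, fell from 1309 ± 13.9 to 904 ± 17.9 FPKM. Psmb8 and Psmb10, subunits of the immunoproteasome, fell from 36.1 ± 0.713 to 26.2 ± 0.913 FPKM and from 29.3 ± 1.795 to 17.4 ± 0.315 FPKM. Lysosomal and endosomal proteases were lower in 12 of 20 and higher in 4, or 7 with granulocyte genes left out of the total. For lysosomal and endosomal genes the median was −0.27 (−0.15 relative to the median gene), with a fry adjusted p of 3.30e-06 and an adjusted p = 0.3141 with an estimated correlation. Ctss, which trims the invariant chain, fell from 173 ± 2.71 to 105 ± 2.53 FPKM, and Ifi30, a lysosomal thiol reductase, from 136 ± 2.59 to 73.7 ± 0.299 FPKM. Of 9 tested genes in the list of co-stimulatory ligands, 3 were higher and 3 lower. Among them were Vsir, which encodes an inhibitor of T cells (52.2 ± 0.974 to 89.98 ± 0.3002 FPKM), and Tnfsf9 (3.67 ± 0.357 to 0.873 ± 0.339 FPKM). Their median was 0.03 (−0.0237 to 0.0890 without single libraries), their mean −0.14, and fry gave no call (adjusted p 0.3959). Fry called them upward under 4 other scalings, with a pseudocount of 5 (adjusted p 0.0440) and without MHCII-lo replicate 2 (0.0087). It called them downward with a replicate block (0.0117) and without MHCII-hi replicate 1 (0.0036), 2 (0.0285) or 3 (0.0041).

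Inflammatory genes went both ways. Of 38 interferon response genes, 9 were higher and 12 lower, without a fry call (adjusted p 0.2119). Their mean was 0.02 and their median −0.06, turning to 0.05 after median-ratio scaling. Fry called the list upward under 4 other scalings and without MHCII-lo replicate 3 (adjusted p 0.000697), and downward at a mean of at least 5 FPKM (6.98e-05). Oas3, an antiviral RNA sensor, rose from 1.97 ± 0.135 to 7.63 ± 0.186 FPKM, and Ifi27l2a fell from 38.6 ± 2.09 to 12.4 ± 0.365 FPKM. Of 28 NF-kB and inflammatory genes, 13 were higher and 12 lower. The NF-kB and inflammatory median was 0.09 (0.21 relative to the median gene), at an adjusted p of 0.0019 by fry and an adjusted p = 0.3076 with an estimated correlation. Fry's upward call was lost at a mean of at least 5 FPKM (adjusted p 0.1533, median −0.18), with a replicate block (0.1643) and without MHCII-hi replicate 1 (0.1752), and turned downward without MHCII-hi replicate 3 (0.0049). Il1b rose from 5.62 ± 0.344 to 78.4 ± 2.596 FPKM, and the chemokine gene Ccl3 and the inhibitor gene Nfkbia fell from 323 ± 4.697 to 145 ± 6.74 FPKM and from 165 ± 2.56 to 89.5 ± 0.422 FPKM. Immediate early and stress genes were lower in 19 of 33 and higher in 9. For immediate early and stress genes the median was −0.13 (−0.01 relative to the median gene), with a fry adjusted p of 3.32e-05 and an adjusted p = 0.5756 with an estimated correlation. The relative median was −0.0357 without MHCII-hi replicate 1, 0.0019 without MHCII-hi replicate 3 and 0.0048 after median-ratio scaling. Fry's downward call was lost after median-ratio scaling (adjusted p 0.1015) and with granulocyte genes left out of the total (0.3514). Atf3, a stress-induced transcription factor, fell from 116 ± 1.85 to 39.98 ± 0.645 FPKM, and Fos fell from 602 ± 3.95 to 424 ± 7.26 FPKM. Genes of niche adhesion and homing were higher in 11 of 19 and lower in 5 (6 lower adjusted over the list alone). Across niche adhesion and homing genes the median came to 0.08 (0.20 relative to the median gene). The fry adjusted p was 0.000236, with an adjusted p = 0.1822 with an estimated correlation. Itgb2, the beta chain of leukocyte integrins, rose from 80.3 ± 1.24 to 213 ± 4.55 FPKM and Itgb7 fell from 73.8 ± 1.09 to 28.1 ± 0.3602 FPKM. Beside the lists of presentation and inflammation, the neutrophil markers took 2.97% and 16.6% of summed FPKM.

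**Figure D2:**
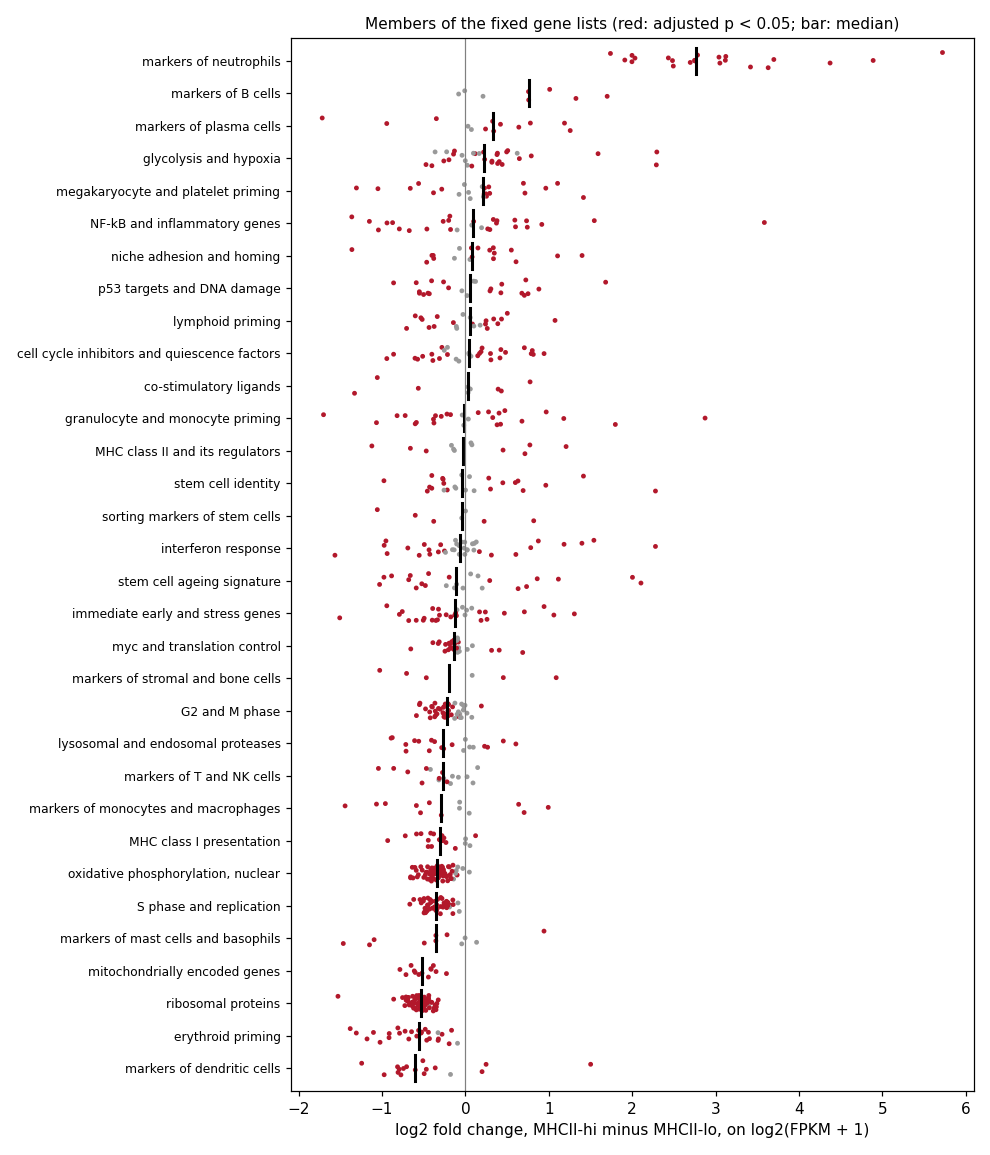
Log2 fold change (MHCII-hi minus MHCII-lo, on log2(FPKM + 1)) of every tested member of 32 fixed gene lists, with 1 point per gene, red where the limma adjusted p was under 0.05 and grey otherwise, and a black bar at each list's median. The 22 neutrophil markers lie to the right of 0 around a median of 2.77, and the 79 ribosomal protein genes lie to the left around −0.53.

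Fry called 28 of the 32 lists, 12 upward and 16 downward, camera called 13 with a preset correlation of 0.01 and 5 with an estimated correlation: the neutrophil list upward and the erythroid, S phase, oxidative phosphorylation and ribosomal protein lists downward. For lists without a count named as such, the numbers adjusted over the list alone were the same as those over all genes. With libraries of a group this alike, small differences passed the test, and fry does not compare a list with other genes.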

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

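Of 2483 values of the 147 named genes under alternatives, 2468 kept direction and side of the threshold, 12 lost their call, all in Ddx3y, Eif2s3y or Tie1, and 3 reversed. These 3 were of Egfl7, never called, whose log2 fold change was 0.0032, or −0.0564 to 0.0614 without a library. Of 541 list values, 480 kept both, 25 reversed, 15 lost and 21 gained a call. Median centring and the total without granulocyte genes were chosen after seeing the data. A pseudocount of 0.1 gave 344 genes at least 2-fold lower, and a pseudocount of 5 gave 215 at least 2-fold higher and 56 lower, as a pseudocount sets the fold of low genes. Lower genes numbered 3123 after median-ratio scaling and 3081 with granulocyte genes left out of the total, where 106 were at least 2-fold lower; the shared factor per library raised all genes of MHCII-hi. Lists called fell from 28 to 13 with camera's preset and 5 with its estimated correlation. Without a library, higher genes numbered 2211 to 2284, lower genes 4336 to 4515, those at least 2-fold higher 433 to 452, those at least 2-fold lower 168 to 175 and lists called 26 to 31.

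Fry's direction turned for lists whose members went both ways, given here with their medians; the cause was not tested. At a mean of at least 5 FPKM these were the interferon response (−0.0753, called downward) and NF-kB (−0.179) lists, and with a pseudocount of 0.1 the ageing signature (−0.147). Plasma cell markers turned under quantile normalization (0.355), median-ratio scaling (0.458), median centring (0.400) and the total without granulocyte genes (0.461), the myc list under median-ratio scaling (−0.0039) and that total (−0.000587), and the sorting markers under both (0.0781 and 0.0812). Leaving out a library turned some fits of plasma cell markers (medians of the 6 fits 0.3085 to 0.3424), the ageing signature (−0.135 to −0.0999), the interferon response (−0.0802 to −0.0433), co-stimulatory ligands (−0.0237 to 0.089) and NF-kB genes (0.0693 to 0.0958). With the replicate block, the co-stimulatory (0.0308) and NF-kB (0.0865) lists turned and 2309 genes were higher, 4662 lower and 27 lists called. Same-numbered libraries did not deviate together (correlations −0.0418, −0.0401 and −0.0422, the lowest for each library). Libraries of a group were nearly identical, so their deviations may be technical. The correlations therefore cannot decide whether the numbers pair the samples. Alternatives for count tables were not run, since the tables hold no counts. Other splits of the 6 libraries into 3 and 3 called at most 0 genes against 7334 in the real one; 1 of 10 splits was as large, and 10 splits are too few for a share under 0.05. Depth is unknown, so for genes near 0 FPKM the lack of a call does not show equal levels.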

Other observations

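The tests in this part were chosen after the results were seen. Granulocyte genes were set apart by stage with 4 lists drawn up after the data were seen. Of 13 secondary granule genes, 13 were higher in MHCII-hi (median log2 fold change 2.43), among them Ltf (188 ± 2.75 to 1018 ± 5.79 FPKM), Camp (404 ± 9.39 to 1521 ± 21.8 FPKM) and Mmp8 (73.9 ± 2.46 to 800.0 ± 3.12 FPKM). Of 16 late neutrophil genes, 15 were higher and 1 lower (median 2.45), among them Retnlg (427 ± 6.38 to 2948 ± 125 FPKM). Primary granule genes, made at the promyelocyte stage, went both ways: 4 of 10 were higher and 5 lower (median −0.06), with Prtn3 at 840.3 ± 18.4 to 646 ± 7.84 FPKM and Ctsg at 1006 ± 5.99 to 1031 ± 24.2 FPKM. Log2 fold changes of these 10 genes ran from −0.384 to 1.0071. Of these 3 lists, 10, 8 and 9 members in the same order are also in a fixed list. Of 13 eosinophil genes, 10 were lower and 2 higher (median −0.83). Siglecf changed little (11.4 ± 0.753 to 10.2 ± 0.0569 FPKM, log2 fold change −0.15) and Ccr3 was higher (1.35 ± 0.0651 to 1.77 ± 0.145 FPKM). Il5ra (2.67 ± 0.565 to 2.22 ± 0.39 FPKM, limma adjusted p 0.2916) did not pass the test. The major basic protein gene Prg2 was among the most abundant transcripts of MHCII-lo at 3670.4 ± 34.5 FPKM and stood at 1570.3 ± 7.11 in MHCII-hi, and Epx, eosinophil peroxidase, went from 293 ± 6.06 to 108 ± 0.218 FPKM and Ear1 from 552 ± 8.49 to 261 ± 6.04 FPKM.

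Immunoglobulin V genes differed in makeup between the fractions. Of 189 V genes with a mean of at least 1 FPKM, 89 were higher and 57 lower in MHCII-hi. Ighv10-3 went from 15.1 ± 1.27 to 116 ± 1.51 FPKM and Igkv1-133 from 5.37 ± 1.27 to 56.1 ± 6.21 FPKM, while Ighv15-2 went from 12.6 ± 1.13 to 2.44 ± 0.3798 FPKM. The summed V gene values were 9107 ± 156 FPKM in MHCII-lo and 10629.5 ± 105 in MHCII-hi. Across these V genes, which are not independent replicates, correlations of log2 values were 0.985 to 0.990 within a group and 0.866 to 0.882 between groups. The median absolute log2 difference between groups was 0.56 for V genes and 0.47 for genes matched on FPKM and length.

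Granulocyte and antibody transcripts were abundant, and many stem cell genes near 0, in all 6 libraries. HSCs as the only origin of the antibody transcripts is argued against by the switched heavy chain genes Ighg1, Ighg2b, Ighg2c and Igha, whose lowest value in any library was 157 FPKM, since HSCs have not switched these genes. RNA of other marrow cells, which a stem cell sort is meant to remove, stays open as a source of the granulocyte transcripts. That the median neutrophil marker exceeded the median stem cell identity gene in 6 of 6 libraries restates the pattern and decides nothing. It also stays open whether another marrow fraction than stem cells was sequenced under the label, which would change what every value of these samples stands for. The median identity gene reached at most 1.665 FPKM in any library, but low values are the pattern itself, and the gates of the sort are not given in the sources used here. Whether HSCs themselves made part of the granulocyte transcripts cannot be told apart from such a mixture, as 15 of 40 identity genes stayed under 1 FPKM in all libraries and low values of them are open to both readings.

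Neutrophil genes were higher and ribosomal protein genes lower in MHCII-hi. FPKM scaling as the whole cause of the ribosomal decrease is argued against. The median nearest to 0 under 4 other scalings was −0.399, from −0.534. The scaled median absolute deviation over the list was 0.106. A larger share of neutrophil RNA in MHCII-hi stays open for the neutrophil genes, since the 22 of 22 markers that were higher are the pattern itself and decide nothing. Such a share as the only difference between these samples is argued against by the V genes. Neutrophils do not transcribe them, and a larger share would multiply them by 1 factor. The lowest V gene correlation within a group exceeded the highest between groups by 0.1022. Multiplying MHCII-lo values by 0.859, the dilution that the neutrophil markers would bring, left the lowest correlation among them at 0.9848. A shared factor nearly fixes that value in advance. If the fractions came from different animals, antibody clones could differ without a change in the share of other cell types. The V genes therefore cannot decide whether the share of other cell types changed. The lineage lists alone did not settle that question. The medians of B cell (0.76, SD 0.638, 8 genes) and dendritic cell markers (−0.60, SD 0.631, 17 genes), picked as the highest and lowest of 6 lineage lists, differed by 1.36. The two-sided exact permutation p across genes, multiplied by the 15 pairs of lists, was 0.0627 for medians and 0.0149 for means, and genes of a list are not independent. A state of MHCII-hi HSCs themselves stays open, since the sort that defines the groups also sets their cell makeup, and the largest ratio of the 4 class II genes between fractions was 2.515.

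Libraries of a group were nearly identical although the fractions differed in V genes. Repeat libraries of 1 preparation of cells or RNA may account for this: the within-group SD of V genes was 0.865 times that of matched genes (0.113 and 0.131), where repertoires of separate single animals would be expected to spread more. The number of animals behind each library is not given, so the ratio does not single out this reading. Replicate numbers as animals whose fractions share B-lineage clones stay open. The V gene correlations across fractions averaged 0.873 for both same-numbered and other libraries. With V genes nearly identical within a group, these averages would lie close with or without pairing and cannot decide this. The lowest same-numbered value minus the highest other was −0.01. That difference decides nothing, since a lowest value minus a highest one tends to lie below 0 with or without weak pairing.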
